A study of Mus musculus with 6 samples.

How the data were processed

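The hippocampi of 6 female mice, 3 controls and 3 with the heterozygous N1768D change in Scn8a, were each measured as 1 library of sorted nuclei with 3′ counting. Age, sex, strain, genotype, replicate number and batch were taken per the labels. The values used were raw UMI counts per gene and barcode, made by the authors with Cell Ranger (version 6.1.2 per the file headers) on mm10 and deposited as filtered matrices. The matrices held 46218 barcodes and 550450212 UMIs. Of their 32285 genes, 32158 (99.6%) were found by identifier in the GENCODE vM21 annotation, which gave coordinates and strands. Sequence of the transcripts was not analysed here.

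Barcodes with under 500 detected genes (397) or over 5% mitochondrial UMIs (25) were left out. Doublets were called per library with Scrublet in scanpy 1.11.5 with an expected share of 6%, which marked 3946 barcodes, between 4.46% (control 2) and 11.4% (control 3) of a library, and these were removed after clusters had been formed. The 41869 kept nuclei numbered 7018, 7387 and 6170 in controls 1, 2 and 3 and 7523, 7210 and 6561 in mutants 1, 2 and 3. Median UMIs per nucleus were 8359, 9238 and 10432 in controls and 7598, 9589 and 8649 in mutants.

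Counts were scaled to 10000 per nucleus, and 2000 variable genes and 30 principal components with 20 neighbours gave 43 Leiden clusters at resolution 1 (scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9). GABAergic nuclei were clustered again into 16 clusters. A cluster took the name of the class whose fixed markers stood highest, if the excess was at least 1 on the log2 scale, led the next class by 0.5 (by 1 unless a marker was among the 10 top genes) and rested on at least 3 markers with a 2-fold excess and 2 among the 50 top genes. A cluster with at least 50% called doublets stayed unnamed. The markers were chosen before the data were examined, as were the gene lists, the models and the alternatives. The naming rule was set after clusters had been seen and before any genotype comparison. Unnamed nuclei made up 16.1%, 20.6% and 17.4% of controls 1, 2 and 3 and 18.0%, 15.4% and 13.4% of mutants 1, 2 and 3, and entered only the sum of all nuclei.

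UMIs were summed per animal and class where every animal had at least 20 nuclei, giving 18 classes and the sum of all nuclei. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit) with batch and genotype in the model. Adjusted p are Benjamini-Hochberg values over the 3586 to 21041 genes tested in a class, with 0.05 as threshold. CPM are TMM-scaled, and ± gives the SD of 3 animals after a mean and the SE after a log2 fold change. Gene lists, 18 in number, were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over 327 tests, and again with the correlation estimated per list. Differences of the genotype effect between classes were tested with limma with trend on the within-animal difference of log2 CPM. Nuclei per class were tested with the edgeR quasi-likelihood model on counts of nuclei with batch, and by exact permutation of the shares.

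The lists held voltage-gated sodium channels, axon initial segment and node genes, potassium channels, calcium and HCN channels, ionotropic glutamate receptors, GABA receptors and transport, immediate early and late response genes, neuropeptides altered in seizure models, reactive astrocyte genes, activated microglia genes, myelin genes, adult neurogenesis, glutamate and potassium clearance, oxidative phosphorylation, mitochondrially encoded genes, heat shock and synaptic vesicle genes.

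Genes were named by a fixed rule. Scn8a was given in every class, and the related alpha subunits in neuronal classes. In all nuclei and in dentate granule, CA1, CA3 and GABAergic neurons up to 10 rising and 10 falling called genes with a mean of at least 10 CPM and the same side in both batches were named, and in other classes up to 3 and 3. Where fewer than 5 passed, the 5 genes of smallest p were eligible, and of each list up to 4 members. Unnamed gene models were skipped unless called in 2 classes. The rule was applied to the block fit as well, and exceptions are marked in the text. The result of 1 gene is not reported here.

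The labels number the animals of each group, and of these only number 1 marks a shared batch. Whether animals with the same number varied together was checked in the data. Over all nuclei the deviations from the group means correlated at 0.737, 0.448 and 0.649 for numbers 1, 2 and 3, against at most 0.158 between other numbers, and 6 of 6 animals were closest to their own number. On these values the number was used as a block in an alternative fit of every class, given beside results where a call or a count moved. In immature neurons the correlations were only 0.0732, 0.0237 and 0.122. In mossy cells, CA2 neurons, committed oligodendrocyte precursors and Vip or Cck neurons 5 of 6 animals were closest to their own number. There number 2 correlated at 0.0291, 0.0618, 0.0257 and 0.0186, below the highest value between other numbers. In these classes the pairing is weakly grounded. The counts of calls with the block had been seen before the correlations were computed.

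Alternatives were a model with no batch term, the block, batch 2 alone, DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low genes, a mean of at least 10 CPM, each animal left out, called doublets kept, nuclei with at least 1000 genes and at most 1% mitochondrial UMIs, resolutions 0.5 (32 clusters) and 2 (61 clusters), and nuclei thinned to 2000 UMIs. For the lists the block was also combined with an estimated correlation, which was chosen after the results were seen. The 10 splits of the animals into 3 and 3 were fitted in the same way. Batch 1 held 1 control and 1 mutant, so without either of them the batch term takes up the other. The fits without control 1 or mutant 1 then rest on batch 2. Together with the fit of batch 2 alone they amount to nearly 1 check.

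The models were tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold per class. They recovered 4% and 48% in all nuclei, 5% and 66% in dentate granule neurons, 32% and 85% in CA1, 23% and 57% in CA3, 1% and 52% in GABAergic and 20% and 58% in immature neurons, 2% and 24% in astrocytes, 0% and 10% in oligodendrocytes and 0% at either size in microglia and CA2 neurons. Recovery was also 0% at either size in parvalbumin, Cajal-Retzius and subicular or cortical excitatory neurons, and 0% and 1% in mossy cells. Unchanged genes were called as well, 30 in the CA1 simulation, 13 in oligodendrocyte precursors, 7 in astrocytes, 6 in mossy cells and at most 5 in any other class. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with Matrix 1.6.5 were used.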

Results

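The hippocampal transcriptome of 6 female C57BL/6J mice was measured at postnatal day 50 by single-nucleus RNA sequencing. Scn8a encodes the voltage-gated sodium channel Nav1.6, which sits at the axon initial segment and sets the firing threshold of many neurons. Of the mice, 3 were Scn8a+/+ controls and 3 carried the heterozygous N1768D protein change in Scn8a, a model of developmental and epileptic encephalopathy, and were sampled before seizure onset according to the labels. Nuclei were sorted on propidium iodide before droplet capture. Batch 1 held control 1 and mutant 1, and batch 2 held controls 2 and 3 and mutants 2 and 3. The deposited matrices held 46218 barcodes, with 84401812 to 98565651 UMIs per animal. After filtering, 41869 nuclei remained, with a median per animal between 7598 UMIs (mutant 1) and 10432 UMIs (control 3). Clusters were named from fixed markers as dentate granule neuron-like, CA1 pyramidal neuron-like and so on, and the names are used without the suffix from here.

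The first question was whether the mutated gene itself was transcribed at another level before seizures. Scn8a (ENSMUSG00000023033, chromosome 15, 100869858 to 101045938 in GRCm38, the assembly also called mm10) was read in each class. In all nuclei together it stood at 387 ± 5.00 CPM in controls and 381 ± 12.6 CPM in mutants (SD, n = 3 animals each). The log2 fold change was −0.02 ± 0.04 (SE) in all nuclei, −0.05 ± 0.04 in dentate granule neurons, −0.03 ± 0.04 in CA1 pyramidal neurons, 0.01 ± 0.05 in CA3 pyramidal neurons and −0.03 ± 0.05 in GABAergic neurons. In immature neurons the value was 0.27 ± 0.12, with 270 CPM in controls and 327 CPM in mutants. None of the 19 tests passed (edgeR quasi-likelihood, Benjamini-Hochberg, smallest adjusted p over classes = 0.518). In microglia, where Scn8a stood at 54.8 CPM in controls and 97.7 CPM in mutants, the call changed without mutant 2, with log2 fold change 1.22 and adjusted p = 0.00849, and without mutant 3 the log2 fold change was 0.21. Counts at the 3′ end do not read the missense change, so the level does not check the genotype labels. The related alpha subunits Scn1a, Scn2a and Scn3a did not pass in any neuronal class either; Scn2a in dentate granule neurons stood at 397 CPM in controls and 417 CPM in mutants.

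**Figure D1:**
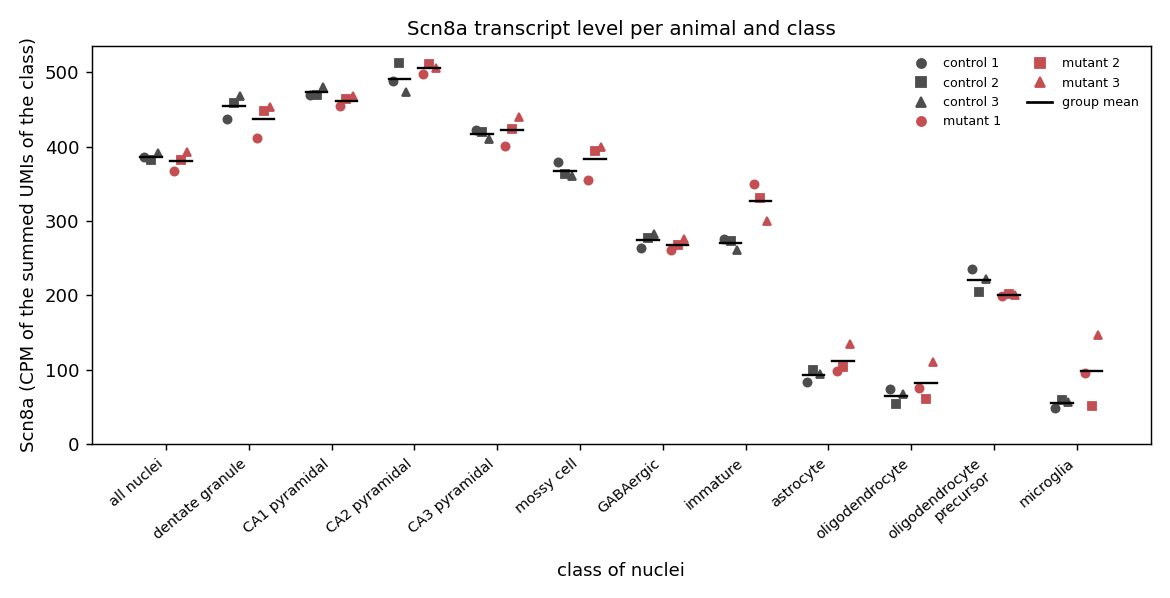
Scn8a level (CPM of the UMIs summed over a class, y axis) in each animal, by class of nuclei (x axis); grey marks are controls, red marks are mutants, the mark's shape gives the replicate number and the line is the group mean. In all nuclei the control mean was 387 CPM and the mutant mean 381 CPM, and in microglia mutant 3 stood highest.

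To ask whether cell composition differed before onset, the share of each class among kept nuclei was compared. Oligodendrocytes made up 11.5% ± 0.429 of nuclei in controls and 14.2% ± 1.43 in mutants (SD, n = 3). Cajal-Retzius neurons, reelin-producing cells of the outer layers, made up 0.657% ± 0.0959 and 0.445% ± 0.0931, and astrocytes 4.77% ± 0.836 and 3.67% ± 0.535. The large neuronal classes lay close together, at 22.5% and 22.9% for dentate granule neurons, 14.1% and 14.8% for CA1 pyramidal neurons and 7.23% and 6.53% for GABAergic neurons. No class passed the count model (edgeR quasi-likelihood, Benjamini-Hochberg, adjusted p = 0.263 for both oligodendrocytes and Cajal-Retzius neurons, 0.324 for astrocytes), while 2 classes lay under 0.05 unadjusted. The two-sided exact permutation test of 3 against 3 animals cannot go below 0.10, and it gave 0.1 for oligodendrocytes and for Cajal-Retzius neurons. It also gave 0.1 for Vip or Cck neurons, at 1.81% in controls and 1.63% in mutants. Without mutant 3, 1 class passed. Shares come from nuclei that went through a sort, and unnamed clusters held between 13.4% (mutant 3) and 20.6% (control 2) of nuclei.

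**Figure D2:**
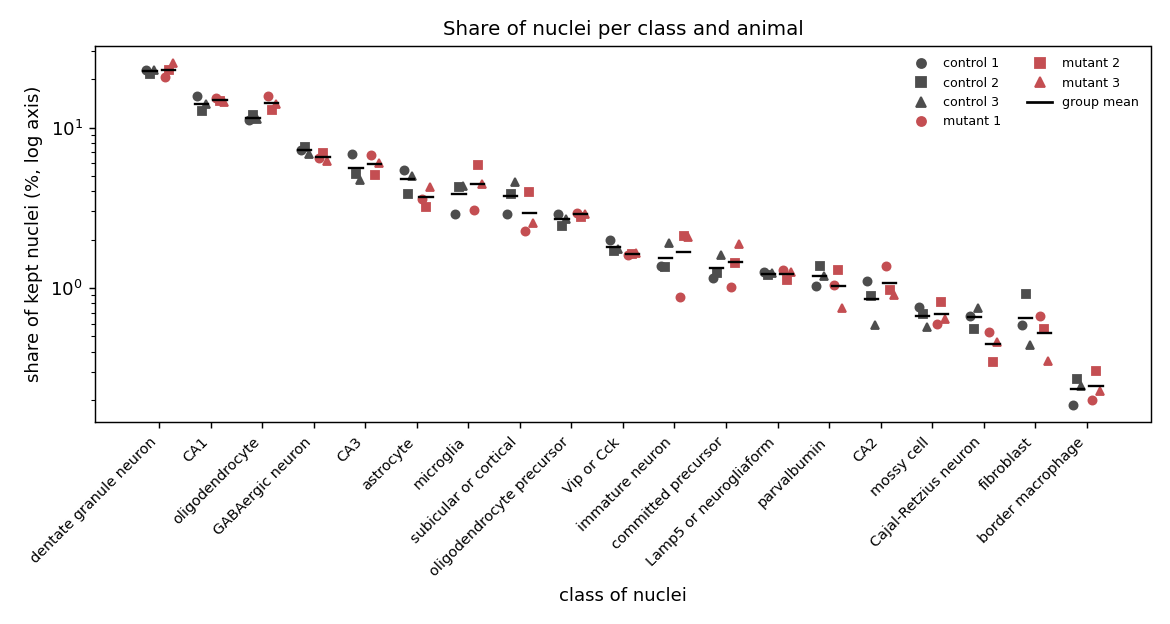
Share of kept nuclei in each class (percent, log axis) per animal, ordered by the control mean; grey marks are controls, red marks are mutants, the mark's shape gives the replicate number and the line is the group mean. Oligodendrocytes averaged 11.5% in controls and 14.2% in mutants.

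To see what the genotype changed in the tissue as a whole, UMIs of all nuclei were summed per animal. Myelin and oligodendrocyte maturation genes rose as a list. Of its 20 measured members 19 were higher in mutants, with a median log2 fold change of 0.28 (camera, adjusted p = 1.5e-11; adjusted p = 0.944 with an estimated correlation). Adjusted over the list alone, 15 members rose, against 0 over all genes. The oligodendrocyte cytoskeleton gene Ermn went from 11.1 to 15.5 CPM (log2 fold change 0.49 ± 0.08), the myelin surface gene Mog from 46.4 to 57.1 CPM (0.30 ± 0.07) and Opalin from 18.9 to 24.9 CPM (0.40 ± 0.09). The list moved beside the oligodendrocyte share of nuclei given above. It also rose in dentate granule neurons (median 0.40, adjusted p = 0.000102), CA1 pyramidal neurons (0.37, 0.000187), CA3 pyramidal neurons (0.42, 0.00136), GABAergic neurons (0.50, 0.000102), astrocytes (0.28, 0.0143) and Vip or Cck neurons (0.38, 0.0494), each with adjusted p = 0.944 with an estimated correlation. Myelin genes do not belong to these cells; their UMIs made up 0.0203% of the UMIs of dentate granule neurons in mutant 1, 0.0183% in mutant 2 and 0.0219% in mutant 3, and 0.0183%, 0.0179% and 0.0166% in controls 1, 2 and 3.

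Among the other lists in all nuclei, activity-induced late response genes rose (16 of 25 higher, adjusted p = 0.0103), with 7 members up adjusted over the list alone and 0 over all genes. Heat shock and dissociation stress genes rose (15 of 17 higher, median 0.09, adjusted p = 0.0338). Genes for glutamate and potassium clearance in astrocytes fell (13 of 14 lower, median −0.12, adjusted p = 0.0226), as did reactive astrocyte genes (13 of 17 lower, median −0.09, adjusted p = 0.0402), beside the astrocyte share given above. Each had adjusted p = 0.944 with an estimated correlation. Immediate early genes had adjusted p = 0.282 in all nuclei and 0.0426 with the replicate number as a block (0.937 with the block and an estimated correlation). No single gene passed in all nuclei (edgeR quasi-likelihood, Benjamini-Hochberg), with 1193 genes at an unadjusted p under 0.05 and 39 called by DESeq2. Without mutant 3 the count was 4. The smallest p belonged to the collagen-binding proteoglycan gene Dcn, at 16.4 CPM in controls and 11.9 CPM in mutants (−0.47 ± 0.06, adjusted p = 0.562, lower in 3 of 3 mutants than in the control of the same number).

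In dentate granule neurons, the largest class, the question was whether the gate of the hippocampal circuit already differed. Here activity-induced late response genes rose as a list, with 16 of 23 measured members higher (median log2 fold change 0.12, camera adjusted p = 0.00341; adjusted p = 0.944 with an estimated correlation). Adjusted over the list alone 3 members rose, and over all genes 0. These were Sorcs3, a sortilin-family receptor (81.6 ± 3.39 to 109 ± 11.6 CPM), the neuronal pentraxin gene Nptx2 (2.13 to 3.75 CPM) and the granule protein gene Scg2 (27.9 to 33.9 CPM). Over all genes tested they had adjusted p = 0.259, 0.318 and 0.318. The list call was lost with nuclei thinned to equal depth (adjusted p = 0.111). Nuclear-encoded oxidative phosphorylation genes (25 of 28 higher, median 0.10, adjusted p = 0.00843) and heat shock genes (14 of 15 higher, median 0.10, adjusted p = 0.00637) rose as well, each with adjusted p = 0.944 with an estimated correlation. The heat shock call was lost without mutant 2 (adjusted p = 0.0787) and mutant 3 (0.0993) and with thinned nuclei (0.111). Neuropeptides and receptors altered in seizure models had a median of 0.07 (8 of 14 higher, adjusted p = 0.325), and over this list alone 2 members rose.

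A single gene passed in dentate granule neurons, Gm15726, which fell by 1.42 ± 0.17 on the log2 scale, from 6.78 to 2.47 CPM, lower in 3 of 3 mutants (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0129). It lies on the antisense strand within Mid1 at the end of chromosome X, so its UMIs are uncertain, and it falls outside the rule for named genes and was picked after its values were seen. DESeq2 called 2 genes. With the replicate number as a block, 40 genes rose and 38 fell. Among those were the glucocorticoid- and activity-responsive kinase gene Sgk1 (37.3 ± 2.99 to 50.5 ± 1.88 CPM, 0.43 ± 0.07, adjusted p = 0.00577), the Ras activator Rasgrp1 (33.3 to 45.9 CPM, adjusted p = 0.00375), Sorcs3 (adjusted p = 0.00589), the calcium-binding protein gene Necab3 (11.3 to 17.3 CPM) and the axon guidance ligand gene Efna5 (31.9 to 42.0 CPM). Falling with the block were the extracellular matrix gene Matn2 (70.3 ± 2.59 to 56.2 ± 4.98 CPM, adjusted p = 0.0101), the anoctamin gene Ano3 (750 ± 11.9 to 631 ± 17.7 CPM, −0.25 ± 0.04, adjusted p = 0.00853) and Scn9a, which encodes the sodium channel Nav1.7 (54.3 ± 3.56 to 43.9 ± 3.03 CPM, −0.30 ± 0.06, adjusted p = 0.0347). Each rise and fall named here was shared by 3 of 3 pairs. With batch in place of the block their adjusted p lay higher, at 0.0958 for both Sgk1 and Ano3 and 0.609 for Rasgrp1. The count with batch was 0 without control 1, control 3 or mutant 1, 2 without control 2, 4 without mutant 3 and 52 without mutant 2, and with 1 animal left out the Gm15726 call stayed only without mutant 2 or mutant 3. It was also lost with no batch term, in batch 2 alone and with thinned nuclei. The class joins 2 clusters whose proportions differed between animals, and clusters were formed on the genes that were then tested.

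In CA1 pyramidal neurons 3 genes rose and 0 fell (edgeR quasi-likelihood, Benjamini-Hochberg). Sntb1, which encodes a syntrophin of the dystrophin complex, rose from 4.55 ± 0.767 to 11.3 ± 3.78 CPM (1.29 ± 0.14, adjusted p = 0.0162). The activity-regulated gene Nrn1 (neuritin) rose from 58.7 ± 3.32 to 77.5 ± 5.88 CPM (0.40 ± 0.05, adjusted p = 0.0425). Igfbp4, an insulin-like growth factor binding protein gene, rose from 11.9 ± 1.06 to 18.8 ± 1.21 CPM (0.66 ± 0.09, adjusted p = 0.0425). All 3 were higher in 3 of 3 pairs, and DESeq2 called 6 genes. With the block 12 rose and 3 fell. The risers then included the growth inhibitor gene Rerg (log2 fold change 0.59, adjusted p = 0.0326), the semaphorin gene Sema4a (17.0 to 24.6 CPM, 0.0272), the potassium channel partner and calcium sensor gene Kcnip3 (98.1 to 121 CPM, 0.0386) and the metabotropic glutamate receptor gene Grm8 (47.8 to 61.9 CPM, 0.0316), and the collagen gene Col6a1 fell from 20.1 to 12.4 CPM (0.0272). Mitochondrially encoded genes rose as a list (9 of 10 higher, median 0.21, adjusted p = 0.00341; adjusted p = 0.944 with an estimated correlation). The calls depended on the animals included. The count was 0 without control 1, control 3 or mutant 1, 1 without control 2, 5 without mutant 2 and 9 without mutant 3, and for Sntb1 the adjusted p was 0.352 without control 1, 0.0703 without control 2, 0.151 without control 3 and 0.355 without mutant 1. Nrn1 and Igfbp4 kept their calls only without mutant 3. With no batch term, with batch 2 alone and with thinned nuclei all 3 calls ended as well (Sntb1 adjusted p = 1.00, 0.402 and 0.0999).

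In CA3 pyramidal neurons no gene passed (edgeR quasi-likelihood, Benjamini-Hochberg), with 786 genes at an unadjusted p under 0.05 and 2 called by DESeq2. Mitochondrially encoded genes, whose transcripts lie outside nuclei, rose as a list, with 10 of 10 higher (median 0.34, adjusted p = 0.000102; adjusted p = 0.944 with an estimated correlation), 0 members passing over the list alone or over all genes, and the call lost with thinned nuclei (adjusted p = 0.745). mt-Co2 stood at 13.2 ± 4.57 CPM in controls and 16.4 ± 4.37 CPM in mutants. As a share of all UMIs of the class the list stood at 0.00642% in mutant 1 against 0.00484% in control 1 and at 0.0112% against 0.00916% in pair 2, but at 0.0104% against 0.0106% in pair 3. The smallest p belonged to the adhesion gene Kirrel3 (254 ± 44.8 and 194 ± 38.7 CPM, −0.39 ± 0.06), Cpne2 (−0.49 ± 0.08) and L3mbtl4 (−1.45 ± 0.25), each with adjusted p = 0.205 and lower in 3 of 3 pairs, and to Sash1 (0.39 ± 0.07) and Tacc1 (0.44 ± 0.08) with adjusted p = 0.216. The count was 1 without control 2, 2 without mutant 2 and 9 without mutant 3.

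In GABAergic neurons, where Scn8a acts beside Scn1a, 1 gene passed. Pcdh11x, an X-linked protocadherin gene of cell adhesion, fell from 136 ± 31.2 to 80.2 ± 8.60 CPM (−0.75 ± 0.07, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000185), lower in 3 of 3 pairs, with log2 ratios of −0.51 in batch 1 and −0.84 in batch 2. The call held with each animal left out in turn and was lost with no batch term (adjusted p = 1.00) and with thinned nuclei (adjusted p = 0.270). With the block 6 genes rose and 4 fell. The risers included Enpp2, which encodes autotaxin (27.6 ± 0.983 to 39.8 ± 3.68 CPM, adjusted p = 0.0153), the guidance gene Sema5a (102 to 128 CPM, 0.0209) and the collagen gene Col14a1 (7.67 to 15.6 CPM, 0.00351). Bmper, a regulator of BMP signalling, fell from 60.4 to 43.4 CPM (0.00857) and the splicing factor gene Khdrbs2 from 260 to 214 CPM (0.0276). Heat shock genes rose as a list (12 of 14 higher, adjusted p = 0.00724; adjusted p = 0.944 with an estimated correlation). The count was 3 without control 1, mutant 1 or mutant 2 and 6 without mutant 3.

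The GABAergic subclasses gave few calls. In Vip or Cck neurons the unnamed transcript A330008L17Rik, picked after its values were seen, rose (202 to 317 CPM, edgeR quasi-likelihood adjusted p = 0.00711), and with the block 6 genes passed, Hs3st4 and Col14a1 rising and Bmper falling among them. The A330008L17Rik call was lost without control 1, control 3 or mutant 1, in batch 2 alone, with thinned nuclei and with coarser clustering, and DESeq2 called 0 genes. With batch the count was 2 without control 1, mutant 1 or mutant 3, 3 without mutant 2 and 4 without control 2. In Vip or Cck neurons the mitochondrially encoded list (5 of 5 higher, median 0.62, adjusted p = 0.000212) and the heat shock list (11 of 13 higher, median 0.15, adjusted p = 0.00843) rose, both with adjusted p = 0.944 with an estimated correlation. In parvalbumin neurons 0 genes passed with edgeR and 0 with DESeq2, with 378 at an unadjusted p under 0.05, and with the block 2. With batch the count was 2 without mutant 2 and 1 without control 2. In Lamp5 or neurogliaform neurons 0 passed with edgeR and 0 with DESeq2, with 465 at an unadjusted p under 0.05, and with the block 4. There the oestrogen receptor gene Esr1 stood at 54.4 ± 5.01 CPM in controls and 20.2 ± 11.4 CPM in mutants (adjusted p = 0.0785, and 0.0105 with the block). With batch the Lamp5 count was 21 without mutant 2, 9 without mutant 3 and 1 without control 1, control 2 or mutant 1.

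**Figure D3:**
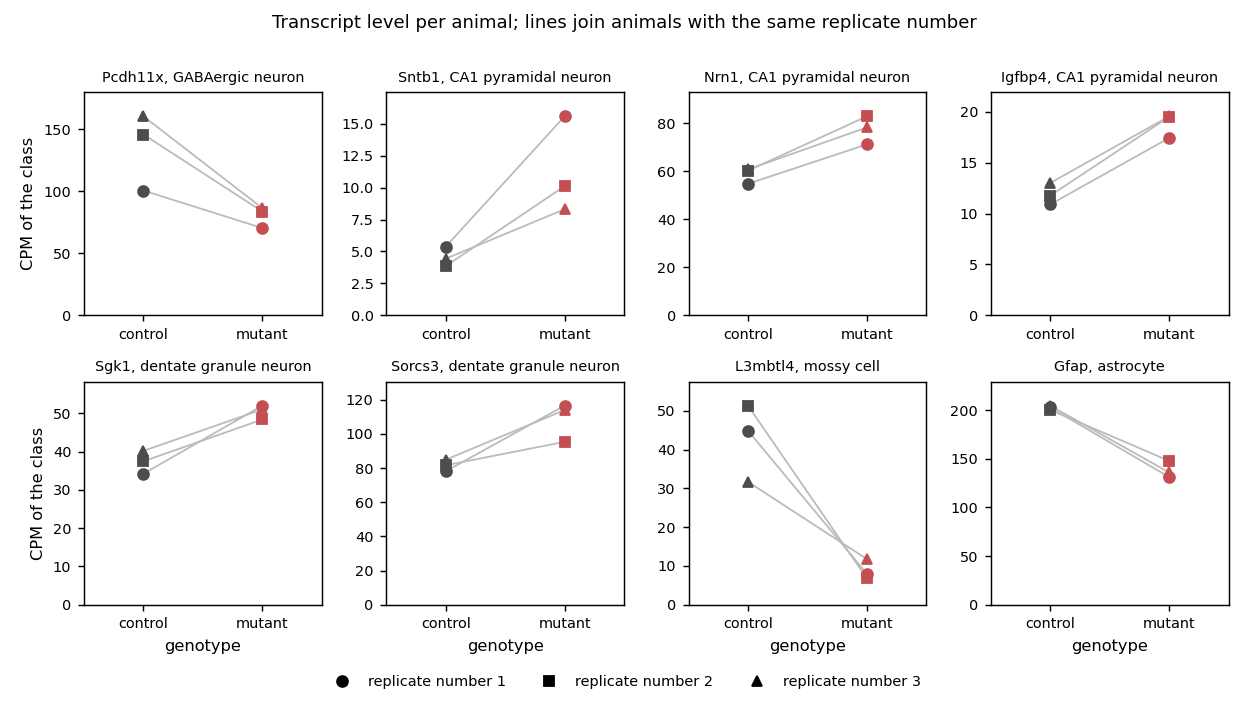
CPM (y axis, from 0) of 8 genes in the class given above each panel, in controls and mutants (x axis); lines join the control and the mutant with the same replicate number. Pcdh11x in GABAergic neurons fell from 136 to 80.2 CPM and Sntb1 in CA1 pyramidal neurons rose from 4.55 to 11.3 CPM, whereas Gfap in astrocytes, at 203 and 138 CPM, and Sgk1 and Sorcs3 in dentate granule neurons did not pass with batch and passed with the replicate number as a block.

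Immature neurons of the dentate gyrus gave the most calls of any class with batch as the covariate, and the comparison asked whether adult-born neurons differed. In these cells 51 genes rose and 8 fell (edgeR quasi-likelihood, Benjamini-Hochberg). Rising genes included the ephrin receptor gene Epha10 (12.9 ± 6.86 to 40.5 ± 3.33 CPM, 1.70 ± 0.36, adjusted p = 0.0122), the synaptic adhesion gene Sdk2 (14.0 to 37.6 CPM, adjusted p = 0.0412) and Arhgef3 (14.6 to 39.3 CPM, adjusted p = 0.0430), each higher in 3 of 3 pairs. Falling genes included Cntnap4, a neurexin-family gene (120 ± 22.6 to 57.5 ± 10.1 CPM, −1.03 ± 0.21, adjusted p = 0.00718), Gpatch1 (49.9 to 22.4 CPM, adjusted p = 0.0394) and Col12a1 (−0.81 ± 0.20, adjusted p = 0.0438). Ionotropic glutamate receptors and their auxiliary subunits rose as a list, with 15 of 21 higher (median 0.21, adjusted p = 0.0161; adjusted p = 0.944 with an estimated correlation). Of these, 3 rose over all genes, among them Grin2a (992 to 1388 CPM) and Shisa6 (241 to 369 CPM), named after their values were seen, and adjusted over the list alone 7 rose and 1 fell. Voltage-gated potassium channels rose too, with 20 of 28 higher (median 0.19, adjusted p = 0.0389; adjusted p = 0.944 with an estimated correlation), 1 member over all genes, Kcnd2, also named after its values were seen, and 2 over the list alone. With the block 6 glutamate receptor genes and 2 potassium channels rose over all genes. With the block, immediate early genes fell as a list, with 5 of 6 lower (adjusted p = 0.0474 against 0.0676 with batch; 0.937 with the block and an estimated correlation).

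Of the 51 genes that rose in immature neurons, 50 had a higher level in dentate granule neurons than in control immature neurons, and 8 of 8 that fell had a lower one. The exception was the proliferation gene Top2a, picked after its values were seen, which rose from 41.5 to 80.8 CPM (1.16 ± 0.28, adjusted p = 0.0430) and stood at 0.248 CPM in granule neurons of mutants. It was higher in 2 of 3 pairs, and its call was lost without control 2, control 3, mutant 2 or mutant 3, with no batch term, with finer clustering and with thinned nuclei. Among the fixed marker genes of other classes, the granule marker C1ql3, picked after its values were seen, rose as well (0.79 ± 0.15, adjusted p = 0.00562). The fixed GABAergic marker Adarb2, picked in the same way, also passed and rose (321 to 486 CPM, log2 fold change 0.64). It stood at 1738 CPM in granule neurons of mutants. With the block 124 genes rose and 30 fell, and DESeq2 called 19. The count was 71 without control 1 or mutant 1, 75 without mutant 2, 18 without mutant 3, 17 without control 2 and 9 without control 3. The Epha10 call was lost without control 2 (adjusted p = 0.150), control 3 (0.151), mutant 2 (0.0524) and mutant 3 (0.0597). The Cntnap4 call was lost without control 2 (adjusted p = 0.134), mutant 2 (0.0669) and with thinned nuclei (0.618), and the calls of Sdk2, Arhgef3, Gpatch1 and Col12a1 were lost with any animal left out, in batch 2 alone and with finer clustering. With thinned nuclei Epha10, Sdk2, Arhgef3 and Gpatch1 were left untested.

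**Figure D4:**
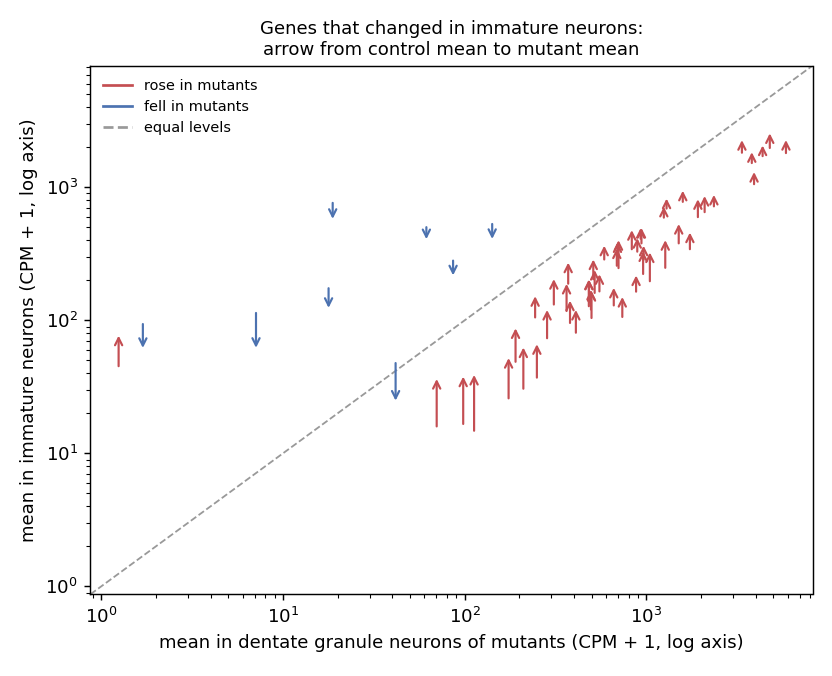
The 59 genes that changed in immature neurons, each an arrow from the control mean to the mutant mean in immature neurons (CPM + 1, log axis) placed at its mutant mean in dentate granule neurons (CPM + 1, log axis); the dashed line marks equal levels. Of the 51 rising genes (red), 50 were higher in dentate granule neurons than in control immature neurons, and 8 of 8 falling genes (blue) were lower.

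The rarer excitatory classes were compared in the same way. In mossy cells L3mbtl4, a gene of the malignant brain tumour repeat family, fell from 42.7 ± 10.0 to 8.85 ± 2.60 CPM (−2.33 ± 0.30, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00169), lower in 3 of 3 pairs, with the call kept with each animal left out in turn. The call was lost in batch 2 alone (−2.27 ± 0.37, adjusted p = 0.0754) and with called doublets kept (−1.69 ± 0.37, 0.777), and with thinned nuclei the filter on low genes left L3mbtl4 untested. It was the single call of its class, and the simulation of mossy cells called 6 unchanged genes. With the block 6 genes passed, among them the giant sarcomere gene Ttn (106 to 229 CPM) and the acid-sensing channel gene Asic2 (237 to 434 CPM) rising and the actin regulator gene Eps8 (68.1 ± 2.45 to 32.2 ± 2.33 CPM) falling. In mossy cells immediate early genes rose as a list, with 9 of 9 higher (median 0.65, adjusted p = 0.0203; adjusted p = 0.944 with an estimated correlation) and 0 past over the list alone or over all genes. The call was lost without control 1 (adjusted p = 0.164), control 3 (0.271) and mutant 2 (0.539) and with doublets kept (0.464). Junb stood at 15.4 ± 5.28 CPM in controls and 24.6 ± 5.04 CPM in mutants. Oxidative phosphorylation genes also rose in mossy cells (20 of 26 higher, adjusted p = 0.0389; adjusted p = 0.944 with an estimated correlation). The gene count in mossy cells was 3 without control 1 or any mutant and 4 without control 2 or 3.

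In CA2 pyramidal neurons 10 genes rose and 2 fell (edgeR quasi-likelihood, Benjamini-Hochberg). The double-stranded RNA binding gene Adarb2 rose from 10.2 ± 1.82 to 41.8 ± 17.9 CPM (2.00 ± 0.25, adjusted p = 1.8e-05) and kept its call with each animal left out, but not with no batch term (0.111) or with doublets kept (0.865). Glis3 (2.69 to 17.9 CPM) and Stxbp6 (5.08 to 20.5 CPM) rose too, and of these Glis3 is a fixed marker of dentate granule neurons, Stxbp6 was among the top genes of their clusters and Adarb2 is a fixed GABAergic marker. Adarb2 also had a high level in dentate granule neurons, at 1738 CPM in mutants, where Stxbp6 stood at 892 CPM. Glis3 and Stxbp6 lost their calls without control 2 (adjusted p = 0.119 and 0.443), without control 3 (0.115 and 0.148), with DESeq2 (0.219 and 0.845) and with doublets kept (0.277 and 0.992), and Stxbp6 with no batch term (1.00). The filter on low genes left Glis3 untested without mutant 2 or mutant 3 and Stxbp6 without mutant 2. With thinned nuclei it left Adarb2, Glis3 and Stxbp6 untested, and 0 of the 12 CA2 calls stayed. The CA2 count was 8 with the block, 3 with DESeq2, 2 without control 2, 3 without control 3, 9 without mutant 2 and 12 to 15 without the other animals. In subicular or cortical excitatory neurons the homeobox gene Meis2 fell from 101 ± 60.6 to 54.3 ± 32.1 CPM (−0.87 ± 0.12, adjusted p = 0.0183), with the call lost without control 1 (0.118), control 3 (0.746) or mutant 1 (0.171), in batch 2 alone (0.121), with no batch term (1.00), with a mean of at least 10 CPM (0.0537) and with doublets kept (0.352). There the count was 4 with the block, 2 with DESeq2, 2 without control 2, 15 without mutant 2 and 7 without mutant 3, and mitochondrially encoded genes rose as a list (7 of 8 higher, adjusted p = 0.0243; adjusted p = 0.944 with an estimated correlation). In Cajal-Retzius neurons 0 genes passed with edgeR and 0 with DESeq2, with 163 at an unadjusted p under 0.05 and 8 calls without mutant 3. With the block, glutamate receptors fell there as a list (12 of 17 lower, adjusted p = 0.0475 against 0.0703 with batch; 0.937 with the block and an estimated correlation).

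In glia the comparison asked whether reactive changes preceded seizures. In astrocytes reactive astrocyte genes fell as a list, with 10 of 11 measured members lower (median log2 fold change −0.47, camera adjusted p = 0.000853; adjusted p = 0.944 with an estimated correlation). Adjusted over the list alone 2 members fell and over all genes 0. These were Gfap, the astrocytic intermediate filament gene (203 ± 2.17 to 138 ± 8.55 CPM, −0.55 ± 0.11, adjusted p = 0.654 over all genes and 0.0144 with the block), and the complement gene C4b (−0.53 ± 0.16). The list call was lost without control 1 (adjusted p = 0.131) or mutant 1 (0.126), in batch 2 alone (0.187) and with thinned nuclei (0.0528). No gene passed over all genes with edgeR or with DESeq2, and 541 lay under an unadjusted p of 0.05. With the block 56 rose and 4 fell, Gfap among those that fell. Gfap is also 1 of the fixed markers that named the class. The count was 40 without mutant 2 and 1 without control 1, control 2 or mutant 1. Mitochondrially encoded genes fell in astrocytes with the block (8 of 10 lower, adjusted p = 0.0274 against 0.231 with batch; 0.937 with the block and an estimated correlation).

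Oligodendrocytes, microglia and astrocytes shared a rise of neuronal gene lists. In microglia potassium channels (24 of 25 higher, median 0.47, adjusted p = 0.000102), ionotropic glutamate receptors (19 of 19, 0.72, 0.000216), axon initial segment genes (14 of 15, 0.66, 0.00968), calcium and HCN channels (15 of 16, 0.60, 0.00253), sodium channels (8 of 10, 0.40, 0.0493) and synaptic vesicle genes (23 of 24, 0.47, 0.000289) rose. In oligodendrocytes synaptic vesicle genes (23 of 26, 0.36, 0.000280), potassium channels (28 of 33, 0.56, 0.000102), GABA receptors and transport (18 of 21, 0.44, 0.00968), sodium channels (11 of 11, 0.47, 0.0333), glutamate receptors (19 of 22, 0.34, 0.00390) and calcium channels (17 of 20, 0.43, 0.0493) rose. In astrocytes 5 such lists rose, glutamate receptors most (18 of 21, 0.38, adjusted p = 0.00213). Each had adjusted p = 0.944 with an estimated correlation. Over all genes 0 members passed, and over the list alone 1 potassium channel and 1 glutamate receptor in astrocytes and 0 in the microglial and oligodendrocytic lists named. With the block, members that rose over all genes were 1 sodium channel, 1 potassium channel and 2 glutamate receptors in microglia and 1 each of the potassium channel, glutamate receptor and GABA lists in oligodendrocytes. In astrocytes they were 4 potassium channels, 3 glutamate receptors and 1 each of the axon initial segment, calcium channel and synaptic vesicle lists. The rise was largest in mutant 3. In its microglia the median nucleus had 0.646% of UMIs in synaptic vesicle genes, against 0.210% in mutant 2, 0.297% in control 3, 0.189% in control 2, 0.377% in mutant 1 and 0.255% in control 1. The mutant thus stood above the control of the same number in 3 of 3 pairs. In oligodendrocytes it did so as well, at 0.361% and 0.287%, 0.256% and 0.240%, and 0.568% and 0.321% in pairs 1, 2 and 3. Without mutant 3 the adjusted p was 0.281 for potassium channels, 0.338 for glutamate receptors, 0.832 for axon initial segment genes and 0.536 for calcium channels in microglia, and 0.538 for synaptic vesicle genes, 0.779 for sodium channels and 0.479 for the GABA list in oligodendrocytes. Without control 2 the axon initial segment (0.191), calcium channel (0.163), sodium channel (0.475) and GABA (0.0815) calls were lost, and without control 1 or mutant 1 the axon initial segment (0.0636 and 0.0577) and sodium channel (0.0567 and 0.0662) calls. The axon initial segment call was also lost in batch 2 alone (0.0548) and the calcium channel call with thinned nuclei (0.0528). With the block the GABA list also rose in microglia (adjusted p = 0.0226 against 0.132 with batch, and 0.937 with the block and an estimated correlation).

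Microglia had 0 calls with edgeR and 0 with DESeq2 (319 at an unadjusted p under 0.05), 60 with the block (58 rose and 2 fell) and 212 without mutant 2. With the block the nicotinic receptor gene Chrna7 rose and Rcbtb2 fell. Oligodendrocytes had 0 calls with edgeR and 0 with DESeq2 (436 under 0.05), 48 with the block (44 rose and 4 fell), 115 without mutant 2 and 1 without control 2. With the block the granule marker Glis3 (log2 fold change 1.41, adjusted p = 0.00799), Srrm3 (1.29, 0.0128) and Slc35f3 (1.14, 0.0349) rose, whereas the ceramide synthase gene Cers2 fell from 158 to 119 CPM (adjusted p = 0.0247) and the aldose reductase gene Akr1b3 from 167 to 113 CPM (0.00799). Oligodendrocytes also had rises of oxidative phosphorylation genes (23 of 28 higher, median 0.15, adjusted p = 0.000707), late response genes (14 of 16, 0.0093) and mitochondrially encoded genes (8 of 8, 0.0259), each with adjusted p = 0.944 with an estimated correlation.

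Oligodendrocyte precursors had 2 falling genes, picked after their values were seen, Gm45025 (121 to 68.8 CPM, edgeR quasi-likelihood adjusted p = 0.00778) and Gm47283 (586 to 417 CPM, 0.01), and DESeq2 called 0. With the block 16 rose and 4 fell, among them the adhesion gene Lingo2 (158 to 294 CPM) rising and the phosphatase gene Inpp4b (800 to 616 CPM, adjusted p = 0.00584) falling. With batch the count was 52 without mutant 2, 4 without mutant 1, 3 without control 1, 1 without control 2 or 3 and 0 without mutant 3, and with 1 animal left out the Gm45025 call stayed only without control 3 or mutant 2. It was also lost with no batch term, in batch 2 alone and with thinned nuclei. The adult neurogenesis list had its smallest p in this class (5 of 7 lower, median −0.10, adjusted p = 0.365, and 0.0498 without mutant 3). In committed oligodendrocyte precursors the glutamate transporter gene Slc1a2 rose from 25.8 ± 5.57 to 89.9 ± 9.34 CPM (1.75 ± 0.24, adjusted p = 0.0179), higher in 3 of 3 pairs. In the same cells the glutamate and potassium clearance list rose (4 of 6 higher, adjusted p = 0.0107; adjusted p = 0.944 with an estimated correlation; 1 member over all genes and 1 over the list alone), with the call lost without control 1 (0.215), mutant 1 (0.228) and mutant 2 (0.0875), in batch 2 alone (0.202), with finer clustering (0.0541) and with doublets kept (0.410). Slc1a2 is an astrocyte marker, and its call was lost with doublets kept (adjusted p = 1.00), with DESeq2 (0.0550), in batch 2 alone (0.138), with finer clustering (0.0615), with thinned nuclei (0.291), and without control 2 (0.0799), control 3 (0.160), mutant 2 (0.13) or mutant 3 (0.0805). The count was 2 without control 1 or mutant 1 and 0 without control 3, mutant 2 or mutant 3. In these cells mitochondrially encoded genes rose (4 of 4 higher, adjusted p = 0.00724; adjusted p = 0.944 with an estimated correlation), and potassium channels with the block (0.0281 against 0.120 with batch, and 0.937 with the block and an estimated correlation). In fibroblasts 0 genes passed with edgeR and 1 with DESeq2 (243 under an unadjusted p of 0.05), 23 with the block and 14 without control 2, 1 without mutant 1 or mutant 3. Their glutamate and potassium clearance list fell (7 of 7 lower, adjusted p = 0.0144; adjusted p = 0.944 with an estimated correlation; 1 member over the list alone), and activated microglia genes, with their smallest p there, had a median of −0.29 (4 of 4 lower, adjusted p = 0.354).

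Whether the genotype acted differently in different neurons was asked with the difference between 2 classes within each animal (limma with trend, Benjamini-Hochberg). Between dentate granule and CA1 pyramidal neurons 6 genes differed. Among them the genotype effect was more positive in CA1 for Dach1 (difference of log2 fold changes −0.66 ± 0.09, adjusted p = 0.00877), Pdzrn4 (−0.56 ± 0.07, 0.00541) and Rerg (−0.62 ± 0.09, 0.0214). It was more positive in granule neurons for Flrt2 (0.38 ± 0.06, 0.0377). Between dentate granule and CA3 neurons 8 genes differed, including the Wnt agonist gene Rspo3 (0.96 ± 0.13, 0.0109), Sgk1 (0.45 ± 0.07, 0.0256) and Eps8 (1.13 ± 0.20, 0.0431). Between dentate granule and GABAergic neurons 6 genes differed, including Efna5 (0.64 ± 0.07, 0.000633), the citron kinase gene Cit (0.79 ± 0.11, 0.00855), Sorcs3 (0.40 ± 0.07, 0.0266) and Ano3 (−0.42 ± 0.06, 0.0124). Between CA1 and CA3 neurons 3 differed, including Rerg (0.67 ± 0.09, 0.00103) and Rspo3 (0.68 ± 0.11, 0.0107). Within single classes the log2 fold change of Rspo3 was 0.23 in granule, −0.05 in CA1 and −0.72 in CA3 neurons. That of Eps8 was 0.13 in granule and −0.99 in CA3 neurons. None of the genes called here passed in a single class of its pair with batch (smallest edgeR adjusted p = 0.0958). Between GABAergic neurons and astrocytes 0 differed, with 506 genes at an unadjusted p under 0.05 and 44 with the block; DESeq2 was not run on differences. With the block the other counts were 39, 19, 18 and 17. With 1 animal left out in turn the difference of Eps8 passed in 0 of 6 fits, those of Rerg and Flrt2 between granule and CA1 neurons in 1, and that of Sgk1 in 2. Those of Dach1, Pdzrn4, Cit, Sorcs3 and Ano3, and of Rspo3 between CA1 and CA3 neurons, passed in 3. Efna5 passed in 4, and Rspo3 between granule and CA3 neurons and Rerg between CA1 and CA3 neurons in 5. Of the 6 fits, those without control 1 and without mutant 1 both rest on batch 2. Over the 5 comparisons together there were 23 calls in 21 genes, 9 calls without control 1, 10 without mutant 1, 11 without control 2 and 220 without mutant 2; with no batch term there were 10.

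A small group of transcripts at the end of chromosome X was lower in mutants in many classes. Gm47283 was lower in 19 of 19 classes and sums and passed in oligodendrocyte precursors (−0.50 ± 0.10, adjusted p = 0.01) and CA2 pyramidal neurons (−0.49 ± 0.10, adjusted p = 0.0234, and 0.0719 with the block). With the block Gm47283 also passed in CA1 pyramidal neurons (adjusted p = 0.0467 against 0.836 with batch), astrocytes (0.0163 against 0.654) and oligodendrocytes (0.0128 against 0.970). Mid1, a ubiquitin ligase gene, was lower in 19 of 19 and passed in immature neurons with the block (0.0331 against 0.102), and Gm15726, antisense to Mid1, in 6 of 6, passing in dentate granule neurons as given above. In GRCm38 Mid1 lies on chromosome X at 169685199 to 170005736 and Gm15726 at 169979047 to 169985232, and the annotation lists Gm47283 on chromosome Y at 90784738 to 90816464. Gm47283 may share reads with near-identical sequence elsewhere and Gm15726 overlaps Mid1, so the identity of these counts is uncertain. The Gm47283 call in oligodendrocyte precursors was lost without control 1, mutant 1 or control 2 (adjusted p = 0.999, 0.999 and 0.960), control 3 (0.0761) and mutant 3 (0.266). With 1 animal left out the CA2 call stayed only without mutant 2. Both calls were lost with no batch term, in batch 2 alone, with DESeq2 and with thinned nuclei.

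Around Scn8a itself, 170 measured genes lay within 5 Mb. None passed in all nuclei (edgeR quasi-likelihood), 11 lay under an unadjusted p of 0.05, which was 6.47% against 5.68% of all genes, and the median log2 fold change was 0.00. Over the tested classes 0 of them passed, and 1 with the block.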

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

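The split tests for the counts of genes and for the differences between classes, both tests of free RNA and the test of gene dosage were chosen only after the result was seen. A test of the difference itself marked 4 results, in which the genotype effect in 1 class differed from that in another. These were dentate granule against CA1 pyramidal neurons with 6 genes, dentate granule against CA3 pyramidal neurons with 8 genes, dentate granule against GABAergic neurons with 6 genes, and CA1 against CA3 pyramidal neurons with 3 genes. The genotype effects on Sgk1, Sorcs3, Efna5 and Rspo3 were more positive in granule neurons than in the class they were compared with, and that on Rerg in CA1 neurons. For Rspo3 the larger change was the fall in CA3 neurons (log2 fold change −0.72, against 0.23 in granule neurons).

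With 10 splits of the 6 animals the share of splits as large cannot be under 0.05. The number of splits with at least as many calls, the real one included, is given with the real count and the highest other count. It was 1 for immature neurons (59, other 57), 4 for dentate granule neurons (1, other 223), 3 for CA1 (3, other 156), 3 for CA2 (12, other 30), 10 for CA3 (0, other 353), 6 for GABAergic neurons (1, other 136), 9 for mossy cells (1, other 8), 7 for subicular neurons (1, other 75) and 10 for Cajal-Retzius neurons (0, other 22). In all nuclei it was 10 (0, other 282). In glia it was 10 for astrocytes (0, other 178), oligodendrocytes (0, other 706) and microglia (0, other 579), 5 for oligodendrocyte precursors (2, other 95) and 7 for committed precursors (1, other 37). For fibroblasts it was 10 (0, other 7), for parvalbumin neurons 10 (0, other 16), for Lamp5 neurons 10 (0, other 74) and for Vip or Cck neurons 8 (1, other 21). For the differences it was 3 for granule against CA1 (6, other 33), 2 for granule against CA3 (8, other 29), 2 for granule against GABAergic (6, other 26), 4 for CA1 against CA3 (3, other 19) and 10 for GABAergic against astrocyte (0, other 70). For the list tests it was 3 (48, other 58) and for nuclei per class 10 (0, other 0). The split of control 1, mutant 1 and mutant 3 against the rest follows a structure of the samples, since it keeps 2 pairs together, and it gave 58 list calls.

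Of the splits that part all 3 pairs there are 4, so with the block a share cannot be under 0.25. The real split gave 78 genes in dentate granule neurons against 0, 0 and 0 in the others, 154 against 0, 1 and 5 in immature neurons, 15 against 0, 1 and 0 in CA1 and 10 against 0, 0 and 1 in GABAergic neurons. Astrocytes (60), oligodendrocytes (48) and microglia (60) gave 0 in each of the others. In mossy cells the real 6 stood against 10, 10 and 3, in parvalbumin neurons 2 against 4, 8 and 9, in committed precursors 1 against 0, 12 and 38 and in CA2 neurons 8 against 1, 6 and 1.

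The first pattern weighed is the set of genes changed in immature neurons. With thinned nuclei the median ratio of log2 fold changes was 1.08, with a scaled median absolute deviation over genes of 0.34, and 53 of 53 measured genes kept their sign. This argues against a greater weight of deep nuclei in the sums. Depth per nucleus otherwise stays open, since classes were named at full depth and the thinned counts were drawn from the same UMIs. Free neuronal RNA stays open, since the median rise of the risen genes in microglia, as a share of that in immature neurons, differed between the pairs of equal number. The share was 50.4% in pair 1, with an error over genes and not animals of 9.52, 8.86% in pair 2 and 39.3% in pair 3. A mix with mature granule neurons or their RNA stays open too, since only 3.39% of the genes moved away from the granule level or ended beyond it. A shift of the immature cells towards maturity predicts the same movement and may also underlie it. Neither predicts the rise of the proliferation gene Top2a away from the granule level. Top2a is 1 gene picked after its values were seen, with a call lost in several fits, so it cannot decide against either. The level of Dcx and of granule markers in single nuclei at a fixed stage could part the mix from the shift.

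The second pattern is the rise of neuronal lists in glia, which was largest in mutant 3. Microglia joined with neurons in 1 droplet are argued against, because the median microglial nucleus carried 2.79 times the synaptic share of the other animals of its batch, whereas joined droplets would be a minority. Free neuronal RNA in the droplets may be the source and stays open. In microglia the markers of 4 of 4 neuronal classes were highest in mutant 3 within its batch, with ratios to the other animals from 1.13 for granule markers to 2.80 for CA3 markers. In oligodendrocytes they were highest there for granule (ratio 1.29) and GABAergic markers (1.05), but not for CA1 (0.944) and CA3 markers (1.10), and in astrocytes for CA1 (1.72) and GABAergic markers (1.65), but not for granule (1.01) and CA3 markers (1.02). Some markers that were not highest had a high level in these glia, such as 2591 to 3080 CPM for CA1 markers in oligodendrocytes in batch 2, which would hide a small share. The level does not account for all of them. In the same oligodendrocytes CA3 markers, not highest in mutant 3, stood at 916 to 1157 CPM. GABAergic markers, highest there, stood at 2734 to 2886 CPM. Empty droplets, which would decide, were not used here, and a change in the glia stays open.

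The third pattern is the lower level of Gm47283, Mid1 and Gm15726. A difference along the whole distal X chromosome is argued against, since 22 genes within 5 Mb before Mid1 had a median log2 fold change of −0.014. Its error of 0.025 was taken over these genes and not over animals. A gene dosage difference at the pseudoautosomal end stays open. The values of Gm47283 over 15 classes that share no nuclei had a weighted mean of −0.45 and did not differ by more than their errors (Cochran Q test across classes, 0.877). The values of Mid1 were less even (0.0351), from −1.12 ± 0.40 in fibroblasts and −0.77 ± 0.19 in microglia to −0.09 ± 0.12 in astrocytes, as were those of Gm15726 over 5 classes (0.0640). Neither lay below the bound of 0.01 set for an exclusion, and the classes come from the same animals and share their errors. It could be a strain or colony difference unlinked to Scn8a, which counting DNA copies would test, and regulation by the genotype was not tested.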

How the results depend on the processing

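The replicate block with an estimated correlation was chosen only after the results were seen. For named genes 3724 values were labelled the same, 174 moved past the threshold, 130 fell back and 2 reversed, and for lists 216, 2, 66 and 0. The 3724 include 218 values from batch 1 alone, which had no test and so kept no side of a threshold. The others kept their side. A gene counts as reversed where its sign turned and either value passed the threshold or both exceeded their SE. Xkr6 in mossy cell reversed to −0.94 and Scn8a in Cajal-Retzius neuron to 0.28, both with finer clustering. Unless said otherwise the cause was not tested.

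With the replicate block the paired counts were 78 in dentate granule neurons (1 with batch), 15 in CA1 (3), 10 in GABAergic (1), 154 in immature neurons (59), 396 over all classes other than dentate granule, CA1, CA3 and GABAergic neurons, immature neurons and GABAergic subclasses included (77), and 137 for differences between classes (23). For Scn8a, nuclei per class and the lists the block changed no call other than those given beside the results. With no batch term the counts were 0 in dentate granule, 0 in CA1 and 0 in GABAergic neurons, 46 over the classes other than those 4 and 10 for differences. In batch 2 alone, with fewer animals, they were 0 in dentate granule, 0 in CA1 and 2 in GABAergic neurons. DESeq2 gave 39 in all nuclei, 2 in dentate granule, 6 in CA1, 2 in CA3, 2 in GABAergic and 19 in immature neurons and 27 over the classes other than those 4. With no filter on low genes they were 69 in dentate granule, 31 in CA1, 87 in CA3, 44 in GABAergic and 117 in immature neurons and 434 over the classes other than those 4. With a mean of at least 10 CPM they were 0 in dentate granule and 0 in CA1. Finer clustering gave 7 in CA1, 27 in immature neurons and 49 over the classes other than those 4, and coarser clustering 34 in immature neurons. Thinned nuclei, with fewer UMIs, gave 1 in all nuclei, 0 in dentate granule, 1 in CA1, 1 in CA3, 16 in immature neurons, 36 over the classes other than those 4 and 23 list calls. With an estimated correlation 0 of 48 list calls stayed, and with the block and an estimated correlation 0 of 54. For lists with little estimated correlation this does not show that correlated genes made the calls. In dentate granule neurons the late response list had an estimated correlation of −0.030, yet its camera p went from 0.000188 to 0.0258. The heat shock list there stood at −0.049. Other lists lay far above the preset 0.01, with 0.776 for glutamate receptors and 0.735 for potassium channels in microglia. Synaptic vesicle genes in oligodendrocytes stood at 0.502 and myelin genes in all nuclei at 0.556. For those lists correlation between genes may have made the calls.

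Leaving out 1 animal gave 0 to 4 genes in all nuclei (highest without mutant 3), 0 to 52 in dentate granule neurons (without mutant 2), 0 to 9 in CA1, 0 to 9 in CA3 and 1 to 6 in GABAergic neurons (each highest without mutant 3), 9 to 75 in immature neurons (lowest without control 3, highest without mutant 2) and 18 to 547 over the classes other than those 4 (the same animals). Scn8a was called in 0 to 1 classes, list calls ran from 19 (without mutant 3) to 47, differences from 9 to 220 (without mutant 2) and classes by nuclei from 0 to 1. In the group left with 2 animals the spread was pooled over groups. Without control 1 or mutant 1 the genotype effect came from batch 2, so these 2 fits are not separate checks.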

Other observations

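All tests named in this part were described above, and the values here were picked after they had been seen. A small unnamed cluster (64 barcodes with called doublets) carried activity-induced genes, with Pcdh8, Inhba, Baz1a, Atf3, Fosb and Nptx2 among its 10 top genes. Such genes can be induced by strong firing, but what induced them in these nuclei was not tested, and neither was the size of the cluster between genotypes. The cluster held 9, 4 and 10 nuclei in controls 1, 2 and 3 and 14, 14 and 11 in mutants 1, 2 and 3.

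Several unnamed clusters varied in size between animals. A cluster led by Npsr1, Pdzrn3 and Gpc6 held 73, 254 and 233 nuclei in controls and 104, 265 and 41 in mutants 1, 2 and 3, and a cluster led by C1qtnf7 and Cpa6 held 62, 211 and 210 and 50, 111 and 38. Both were smallest in control 1, mutant 1 and mutant 3. A cluster led by Ano1 with Zic1 and Zic4 held 18, 102 and 0 nuclei in controls and 245, 57 and 19 in mutants. A cluster led by mitochondrially encoded genes held 64, 53 and 86 nuclei in controls and 107, 73 and 178 in mutants.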
